A study of Mus musculus with 12 samples.

How the data were processed

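RNA of the mouse macrophage-like line RAW264.7 was sequenced in 12 libraries, 3 each of untreated cells, cells given 32 µg/mL resveratrol, cells infected with Salmonella Typhimurium (multiplicity 20, 1 h, then gentamicin), and infected cells given resveratrol, with treatments held for 6 h. Per the labels' protocols, polyadenylated RNA was captured on oligo-T beads, fragmented and copied to cDNA with random primers. Per the submitters' processing notes, reads were trimmed with fastp, aligned to GRCm38 with HISAT2 2.0.5 and counted with featureCounts 1.5.0-p3, and DESeq2 1.20.0 was used. The labels state neither the number of separate cultures behind a group, nor whether cells without resveratrol received its solvent, nor the order of resveratrol and infection.

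The authors deposited a table with a value in FPKM for each of 54532 genes and 12 libraries, together with gene length and position. Groups were taken from the sample titles, and columns were matched to samples by the library names in the descriptions. Dividing out gene length gave whole read numbers for 100% of values in each library within a tolerance of 0.01, so reads per gene could be recovered, with totals from 17003166 to 18122399. The deposited FPKM had not been made with those totals. Library sizes of 14984761 to 20767732 fitted the values, each equal to the median-of-ratios size factor of the recovered reads times the geometric mean total of 17442335, so the deposited FPKM already carried that scaling. On a 1 kb transcript, 1 read was worth 0.0482 to 0.0667 FPKM. Identifiers were compared with GENCODE release 21 for GRCm38, where 54495 of the genes were present, 53585 with the same start and end and 53921 with the same symbol. Libraries of a group were checked for duplicates, and none shared its values with another (0 identical pairs).

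Tests used R 4.3.3 with limma 3.58.1, and tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes with at least 1 FPKM in at least 3 of the 12 libraries were kept (11706), and values were transformed as log2(FPKM + 1). A group-means model over all 12 libraries (8 residual degrees of freedom, prior 3.34) was fitted with eBayes and an intensity trend. Contrasts were infected, resveratrol and doubly treated against untreated cells, doubly treated against infected and against resveratrol cells, and the interaction of infection and resveratrol. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast, without a fold minimum. The samples, groups, tests, gene lists, the rule for named genes and most alternatives were set before the data were examined.

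Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data, adjusted over the 26 lists of a contrast. These covered inflammatory cytokines, chemokines, NF-kB feedback and signalling genes, interferon-stimulated genes, immediate-early and MAPK feedback genes, pattern recognition receptors and adaptors, inflammasome and lytic death genes, antimicrobial effectors, alternative activation and anti-inflammatory genes, NRF2 and antioxidant genes, and integrated stress response and unfolded protein response. Further lists were heat shock genes, p53 target genes, S-phase and DNA replication genes, G2 and mitosis genes, cholesterol synthesis and uptake, liver X receptor targets and lipid efflux, glycolysis, oxidative phosphorylation, autophagy genes, and lysosome genes. The rest were sirtuins and mitochondrial biogenesis, aryl hydrocarbon receptor targets, macrophage identity markers, osteoclast markers, and markers of other cell types. Members below the filter were counted as not tested, and 1 symbol was absent from the table. Shares of summed FPKM in mitochondrial, histone and ribosomal protein genes were computed per library and compared by exact permutation.

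Named genes followed a fixed rule. A panel (Tnf, Il1b, Il6, Il10, Nos2, Ptgs2, Cxcl10, Ccl5, Hmox1, Nqo1, Cdkn1a and Sirt1) was named whatever its result. Each comparison of a pair of groups added up to 8 called protein-coding genes with the largest rise and up to 8 with the largest fall, with a group mean of at least 5 FPKM and libraries that did not overlap, leaving out Gm and Rik symbols. The interaction added up to 6 in each direction without the overlap condition. Each list added up to 4 called members with the largest change, or up to 2 uncalled members where none was called. In the text, fewer may be named from the top, and some genes that the rule selects are not reported here. Exceptions are Cyp1a1, Ahr, Arg1, Mrc1, Chil3 and Retnla. So are genes given as examples of calls that opposed or extended infection or moved alike in a pair of comparisons. Genes in the last section, chosen afterwards, are exceptions too.

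For genes with no read in a group, the fold is a lower bound at a floor of 3 reads over the group, and for 1 to 3 reads it is a ratio with an exact 95% counting interval. Calls that opposed or extended the infection response were counted between contrasts that share libraries, and the covariance and correlation that sharing alone gives were obtained from 50 simulated sets of 12 libraries without group effects. Both were also computed with the infected libraries divided between the comparisons, a check added after the data were seen. GC content came from the longest GENCODE transcript (known for 11684 tested genes, 99.8%), and its correction subtracted lowess trends of span 0.3.

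The procedure was tested on simulated data with 50 genes changed at each absolute log2 fold change of 0.5, 1, 1.5 and 2 in each comparison. In that order, 9, 33, 44 and 46 were recovered for infected and 4, 31, 45 and 46 for resveratrol against untreated cells. Doubly treated cells gave 7, 30, 42 and 45 against infected and 14, 34, 45 and 46 against resveratrol. Against untreated they gave 10, 26, 45 and 45. Of 11312 to 11352 unchanged genes per comparison 7, 14, 5, 6 and 3 were called (5.04%, 10.0%, 3.88%, 4.14% and 2.33% of calls). Median fitted sizes for infected against untreated cells were 0.39, 0.88, 1.30 and 1.77, smaller than the true ones. A chemokine list shifted by 0.75 was found at adjusted p = 3.24e-11, with 0 of the 25 others called. A test with 1 shifted list cannot show how often correlated genes give false list calls.

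Alternatives set in advance were pseudocounts of 0.1 and 5, other filters, equal sums per library, quantile normalization, median-of-ratios scaling, robust or untrended moderation, array weights, the compared groups alone, protein-coding genes alone, a fold minimum, the replicate number as a block, and leaving out each library. Added after the data were seen were own totals, equal sums without mitochondrial genes or without the 100 highest genes, voom on the recovered reads, the GC and length correction, gene-by-gene array weights, and leaving out the libraries numbered 2. No outlier test was run within groups of 3, and single libraries were instead weighted or left out.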

Results

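The deposited table held 54532 genes for 12 libraries of the mouse macrophage-like line RAW264.7, with 3 libraries in each of 4 groups. These were untreated cells, cells given 32 µg/mL resveratrol, cells infected with Salmonella Typhimurium at a multiplicity of 20 for 1 h, and infected cells given resveratrol, with treatments held for 6 h. The protocol does not say whether resveratrol came before, during or after infection. Totals ran from 17003166 to 18122399 reads, and 11706 genes passed the expression filter and were tested. Libraries of a group correlated at 0.951 to 0.990, against 0.843 to 0.942 between groups. The first principal component (37.5% of variance) placed resveratrol cells opposite infected cells, and the next (30.7%) placed untreated cells opposite infected cells given resveratrol. The median SD of a gene within a group was 0.0925 log2 units in untreated, 0.192 in resveratrol, 0.221 in infected and 0.139 in doubly treated cells. Mitochondrially encoded genes took the most FPKM in the library numbered 2 of each group, at 11.2%, 16.4%, 16.4% and 15.4% in the order untreated, resveratrol, infected and both. Gene values are FPKM as mean ± SD of 3 libraries. Fold changes are differences of log2(FPKM + 1) ± standard error, a scale that understates changes of genes near 0, and adjusted p-values are from limma. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these samples.

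**Figure D1:**
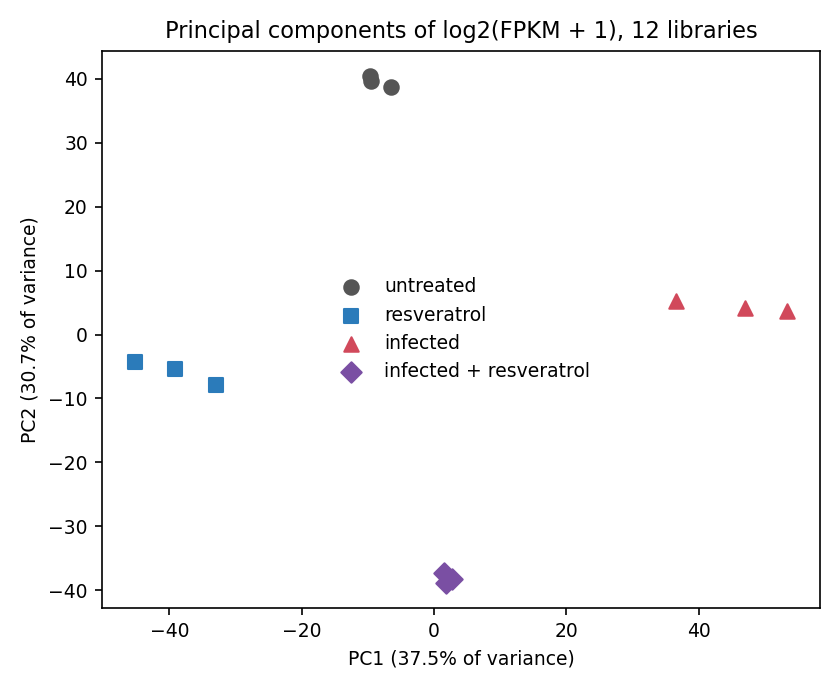
Principal components of log2(FPKM + 1) over the 11706 tested genes, with PC1 (37.5% of variance) on the horizontal and PC2 (30.7%) on the vertical axis in arbitrary units. Each point is a library and colour and shape give the group, and the 3 libraries of each group lie together and apart from the other groups.

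Infection raised cytokine genes and Ptgs2. Csf3, which encodes the granulocyte growth factor G-CSF, stood at 0.0273 ± 0.0473 FPKM in untreated and 210.3 ± 24.5 FPKM in infected cells (7.68 ± 0.20, adjusted p = 6.40e-10). With 2 reads over the untreated libraries, its ratio was 7741 with a 95% counting interval of 2142 to 63922. Il1rn, the antagonist of the interleukin-1 receptor, rose from 5.38 ± 0.449 to 822 ± 124 FPKM (adjusted p = 6.33e-11). Il33 had no read in untreated cells and 79.6 ± 19.0 FPKM in infected cells, at least 3942-fold higher (6.30 ± 0.15, adjusted p = 3.92e-10). Il1b went from 0.0200 ± 0.0173 to 49.7 ± 10.1 FPKM (5.62 ± 0.17, adjusted p = 1.77e-09), a ratio of 2446 with a counting interval of 677 to 20208. S100a8, a calprotectin subunit, was higher (5.50 ± 0.58, adjusted p = 2.87e-05). Ptgs2, the inducible cyclooxygenase, rose from 25.6 ± 2.44 to 1117 ± 301 FPKM (5.36 ± 0.17, adjusted p = 1.77e-09). Il6 had no untreated read and 16.5 ± 5.85 FPKM after infection, at least 686-fold higher (4.08 ± 0.21, adjusted p = 1.23e-07). Floors and intervals of this kind, here and below, cover counting error alone, and a floor is 3 reads over a group.

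Among falls with infection, Egr2 went from 15.4 ± 1.38 to 0.468 ± 0.0753 FPKM (-3.48 ± 0.13, adjusted p = 8.25e-09) and Egr1 from 99.0 ± 7.62 to 8.51 ± 1.71 (-3.41 ± 0.20, adjusted p = 3.13e-07). Fosb (-2.87 ± 0.20, adjusted p = 1.31e-06), Cd24a (-2.76 ± 0.13, adjusted p = 6.15e-08) and Klf2 (-2.74 ± 0.32, adjusted p = 5.79e-05) were lower as well. Of the panel of genes named in advance, Nos2 rose from 0.0261 ± 0.0131 to 22.8 ± 4.77 FPKM (4.52 ± 0.15, adjusted p = 2.72e-09) and Hmox1 from 90.5 ± 4.45 to 1252 ± 299.7 (3.75 ± 0.15, adjusted p = 1.41e-08). Il10 rose from 0.206 ± 0.181 to 4.23 ± 1.10 FPKM (2.11 ± 0.18, adjusted p = 7.21e-06) and Ccl5 from 11.3 ± 1.06 to 90.5 ± 24.7 (2.87 ± 0.44, adjusted p = 0.000481). Cdkn1a was higher (1.18 ± 0.15, adjusted p = 0.000110). Not called were Tnf (78.4 ± 9.18 and 104 ± 14.2 FPKM, 0.40 ± 0.25, adjusted p = 0.241), Cxcl10 (-0.40 ± 0.21, adjusted p = 0.172) and Sirt1 (0.34 ± 0.15, adjusted p = 0.107). Nqo1 lay below the expression filter, with means of 0.148 ± 0.134, 0.185 ± 0.111, 0.0668 ± 0.0597 and 0.244 ± 0.116 FPKM in untreated, resveratrol, infected and doubly treated cells.

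Inflammatory cytokines had 9 higher, 1 lower and 5 not called of 15 (9 and 2 adjusted over the list alone). For inflammatory cytokines camera gave adjusted p = 7.00e-06, and adjusted p = 0.177 with an estimated correlation. Csf3, Il1b, Il1a (4.87 ± 0.17, adjusted p = 4.04e-09) and Lif (4.62 ± 0.14, adjusted p = 1.77e-09) moved most. Chemokines had 9 higher, 0 lower and 2 not called of 11 (9 and 0 adjusted over the list alone). For chemokines camera gave adjusted p = 1.84e-06, and adjusted p = 0.0587 with an estimated correlation. Cxcl2 (3.23 ± 0.43, adjusted p = 0.000186) and Ccl3 (3.03 ± 0.31, adjusted p = 2.31e-05) moved most. NF-kB feedback and signalling genes had 11 higher, 0 lower and 9 not called of 20 (12 and 0 adjusted over the list alone). For NF-kB genes camera gave adjusted p = 3.91e-05, and adjusted p = 0.0587 with an estimated correlation. Bcl3 (2.41 ± 0.12, adjusted p = 1.23e-07) and Zc3h12a (2.36 ± 0.18, adjusted p = 3.09e-06) moved most. Inflammasome and lytic death genes had 7 higher, 1 lower and 6 not called of 14 (9 and 1 adjusted over the list alone). For inflammasome genes camera gave adjusted p = 0.00155, and adjusted p = 0.131 with an estimated correlation. Naip2 (adjusted p = 9.05e-05) moved most. Alternative activation and anti-inflammatory genes had 5 higher, 2 lower and 1 not called of 8 (5 and 2 adjusted over the list alone). For alternative activation genes camera gave adjusted p = 0.00243, and adjusted p = 0.131 with an estimated correlation. Il1rn and Il4ra (3.16 ± 0.14, adjusted p = 3.12e-08) moved most. Pattern recognition receptors and adaptors had 10 higher, 5 lower and 7 not called of 22 (10 and 5 adjusted over the list alone). For pattern recognition receptors camera gave adjusted p = 0.0613. Cd14 (1.86 ± 0.11, adjusted p = 3.27e-07) moved most. Interferon-stimulated genes had 6 higher, 6 lower and 6 not called of 18 (6 and 7 adjusted over the list alone). For interferon-stimulated genes camera gave adjusted p = 0.895, and median, mean and test differed in sign. Oasl1 (1.99 ± 0.12, adjusted p = 3.23e-07) and Isg15 (1.56 ± 0.21, adjusted p = 0.000177) moved most. The direction of their test turned upward under equal sums and under own totals. Immediate-early and MAPK feedback genes had 8 higher, 8 lower and 2 not called of 18 (8 and 8 adjusted over the list alone). For immediate-early genes camera gave adjusted p = 0.694. Dusp5 (4.44 ± 0.11, adjusted p = 3.92e-10) and Egr2 moved most. Their test also turned upward under equal sums and under own totals.

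Proliferation genes were lower in infected cells. S-phase and DNA replication genes had 1 higher, 15 lower and 8 not called of 24 (1 and 16 adjusted over the list alone). For S-phase genes camera gave adjusted p = 6.14e-05, and adjusted p = 0.0587 with an estimated correlation. Uhrf1 (-0.97 ± 0.11, adjusted p = 5.07e-05) and Mcm7 (-0.84 ± 0.09, adjusted p = 3.62e-05) moved most. G2 and mitosis genes had 0 higher, 15 lower and 5 not called of 20 (0 and 16 adjusted over the list alone). For G2 and mitosis genes camera gave adjusted p = 2.93e-06, and adjusted p = 0.0587 with an estimated correlation. Plk1 (-1.34 ± 0.18, adjusted p = 0.000195) and Aurkb (adjusted p = 1.05e-05) moved most. Lysosome genes had 1 higher, 10 lower and 12 not called of 23 (2 and 13 adjusted over the list alone). For lysosome genes camera gave adjusted p = 0.0112, and adjusted p = 0.0587 with an estimated correlation. Atp6v1h (0.82 ± 0.17, adjusted p = 0.00335) moved most. Oxidative phosphorylation genes had 0 higher, 10 lower and 15 not called of 25 (0 and 11 adjusted over the list alone). For oxidative phosphorylation genes camera gave adjusted p = 0.00238, and adjusted p = 0.316 with an estimated correlation. Sdhd (-0.67 ± 0.13, adjusted p = 0.00211) moved most. Integrated stress response and unfolded protein response genes had 11 higher, 3 lower and 10 not called of 24 (12 and 3 adjusted over the list alone). For integrated stress response genes camera gave adjusted p = 0.00483, and adjusted p = 0.0587 with an estimated correlation. Vegfa (2.31 ± 0.13, adjusted p = 2.20e-07) and Trib3 (1.80 ± 0.18, adjusted p = 2.10e-05) moved most. Heat shock genes had 5 higher, 0 lower and 5 not called of 10 (6 and 0 adjusted over the list alone). For heat shock genes camera gave adjusted p = 0.0210, and adjusted p = 0.177 with an estimated correlation. Quantile normalization removed the heat shock call (adjusted p = 0.0985).

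NRF2 and antioxidant genes had 7 higher, 4 lower and 10 not called of 21 (8 and 5 adjusted over the list alone). For NRF2 and antioxidant genes camera gave adjusted p = 0.142, and median, mean and test differed in sign. Hmox1 and Slc7a11 (adjusted p = 2.26e-07) moved most. Under equal sums 6 of these were higher and 7 lower. Antimicrobial effectors had 5 higher, 7 lower and 3 not called of 15 (5 and 7 adjusted over the list alone). For antimicrobial effectors camera gave adjusted p = 0.791, and median, mean and test differed in sign. Nos2 and Acod1 (4.14 ± 0.12, adjusted p = 1.61e-09) moved most. Liver X receptor targets and lipid efflux genes had 2 higher, 6 lower and 5 not called of 13 (2 and 7 adjusted over the list alone). For liver X receptor targets camera gave adjusted p = 0.0947. Abca1 (adjusted p = 6.78e-09) and Abcg1 (-2.17 ± 0.22, adjusted p = 2.11e-05) moved most. Glycolysis genes had 2 higher, 3 lower and 12 not called of 17 (2 and 3 adjusted over the list alone). For glycolysis genes camera gave adjusted p = 0.724, and median, mean and test differed in sign. Slc2a1 (1.87 ± 0.11, adjusted p = 3.11e-07) moved most. After a GC and length correction 5 of these were higher and 2 lower. Autophagy genes had 7 higher, 1 lower and 17 not called of 25 (6 and 1 adjusted over the list alone). For autophagy genes camera gave adjusted p = 0.264. Sqstm1 (1.27 ± 0.12, adjusted p = 1.36e-05) moved most. Under equal sums 3 of these were higher and 5 lower.

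Cholesterol synthesis and uptake genes, p53 target genes, macrophage identity markers, sirtuins and mitochondrial biogenesis genes, aryl hydrocarbon receptor targets and osteoclast markers were not called either. Of 22 markers of other cell types, S100a8 alone was tested, so that list repeats its value.

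In all, 4161 genes were called between infected and untreated cells, 2012 higher and 2149 lower, with 489 and 387 at an absolute log2 fold change of at least 1. Groups did not overlap for 5901 genes (50.4%, where chance gives 10%). The share of calls that were higher was 48.4%. It was 26.8% with values scaled to equal sums and 30.6% with each library scaled by its own total, scalings that moved the median of all genes by -0.16 and -0.14. Log2 fold changes correlated with GC content at a Spearman rho of -0.366 across genes, which are not independent replicates.

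**Figure D2:**
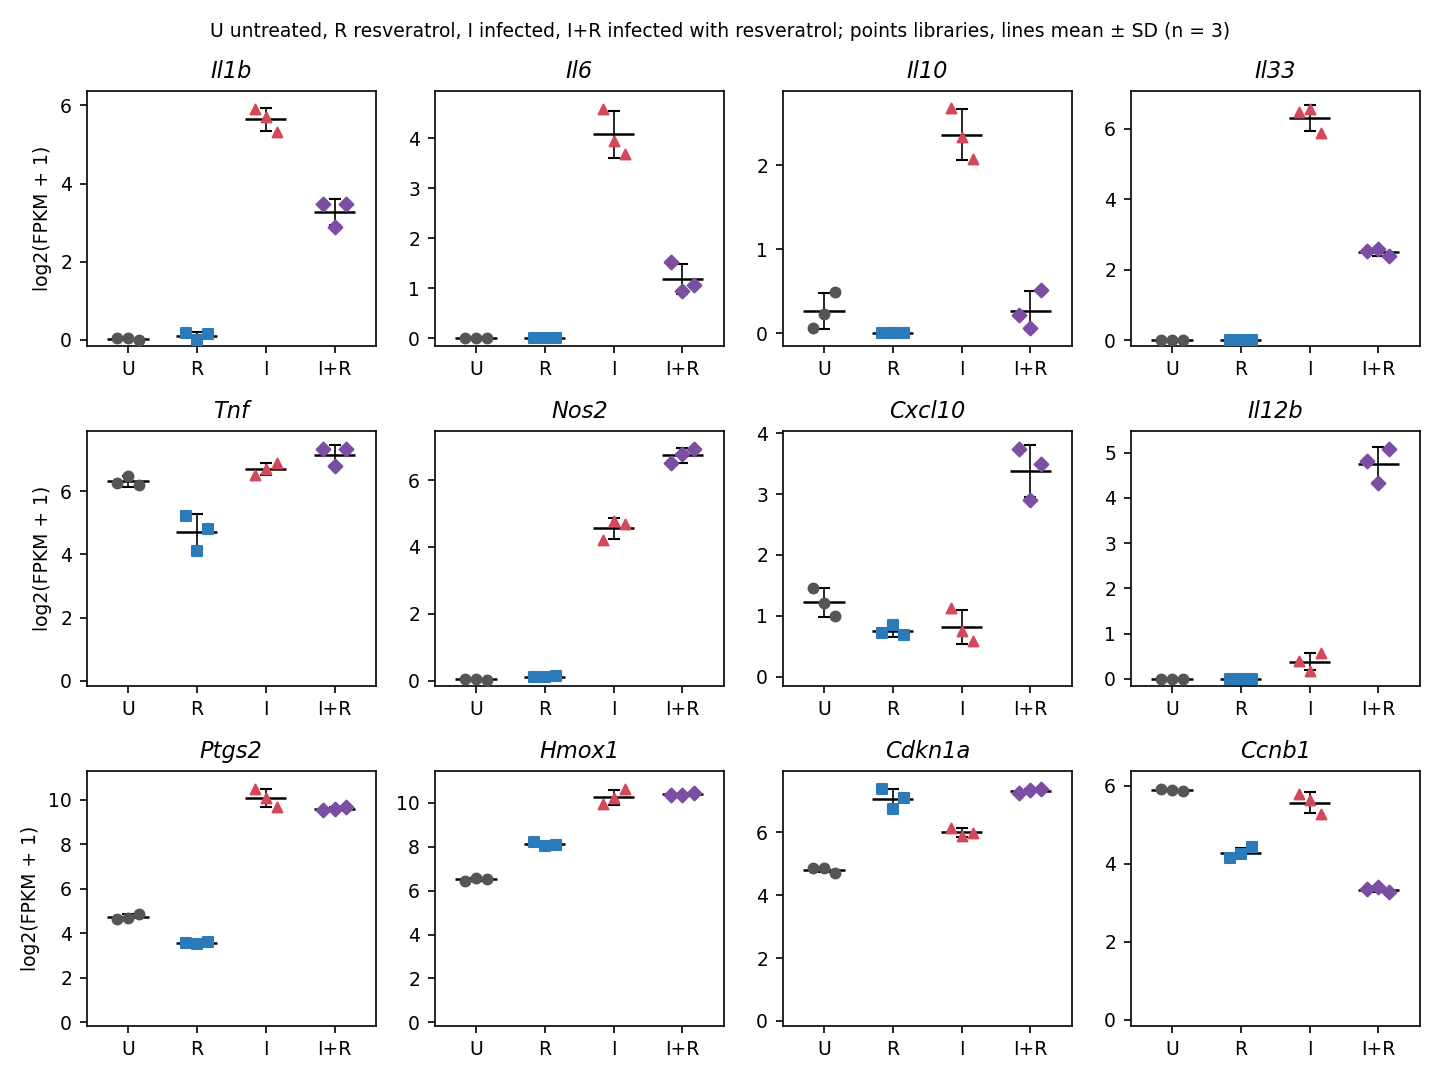
Expression of 12 genes as log2(FPKM + 1) on the vertical axis in untreated (U), resveratrol (R), infected (I) and infected cells given resveratrol (I+R) on the horizontal axis. Points are libraries and lines are mean ± SD (n = 3), and Il33 stands at 79.6 ± 19.0 FPKM in infected against 4.65 ± 0.395 FPKM in doubly treated cells, where Nos2 goes from 22.8 ± 4.77 to 107 ± 15.5 FPKM.

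In cells without bacteria, resveratrol raised stress and p53 target genes. Ddit4, an inhibitor of mTORC1 signalling, rose from 0.591 ± 0.206 to 34.8 ± 14.0 FPKM (4.43 ± 0.25, adjusted p = 5.31e-07). Trp53inp1 rose from 0.395 ± 0.0607 to 22.2 ± 4.18 FPKM (4.04 ± 0.15, adjusted p = 1.35e-07) and Trib3 from 1.85 ± 0.294 to 39.6 ± 3.64 (3.83 ± 0.18, adjusted p = 2.17e-07). Phlda3 (3.12 ± 0.28, adjusted p = 1.34e-05), Epha2 (2.92 ± 0.13, adjusted p = 1.99e-07) and Pdcd4 (2.87 ± 0.19, adjusted p = 1.84e-06) followed. So did the glutathione-degrading enzyme gene Chac1 (2.70 ± 0.17, adjusted p = 1.19e-06). The largest fall was that of Plau, which encodes urokinase, from 270.3 ± 18.3 to 19.1 ± 3.38 FPKM (-3.77 ± 0.17, adjusted p = 1.99e-07). Next came the monocyte chemoattractant gene Ccl2, from 19.0 ± 0.981 to 0.734 ± 0.648 FPKM (-3.61 ± 0.25, adjusted p = 2.19e-06). Ltb (-3.26 ± 0.13, adjusted p = 1.99e-07), Egr2 (-2.93 ± 0.13, adjusted p = 1.99e-07) and the potassium channel gene Kcnn4 (-2.65 ± 0.20, adjusted p = 4.87e-06) were also lower.

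From the panel, Tnf fell from 78.4 ± 9.18 to 26.4 ± 10.0 FPKM (-1.60 ± 0.25, adjusted p = 0.000481) and Ptgs2 from 25.6 ± 2.44 to 10.9 ± 0.405 (-1.15 ± 0.17, adjusted p = 0.000291). Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose from 27.3 ± 1.60 to 136 ± 30.2 FPKM (2.25 ± 0.15, adjusted p = 1.48e-06). Hmox1 rose from 90.5 ± 4.45 to 276 ± 15.2 FPKM (1.60 ± 0.15, adjusted p = 2.15e-05) and the deacetylase gene Sirt1 from 6.84 ± 0.547 to 10.3 ± 1.64 (0.52 ± 0.15, adjusted p = 0.0189). Cxcl10 (-0.47 ± 0.21, adjusted p = 0.105) and Ccl5 (0.08 ± 0.44, adjusted p = 0.906) were not called. Neither were Il1b, Il10 and Nos2, with 9, 0 and 22 reads over the resveratrol libraries, and Il6 had no read in either group.

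Among the lists below, resveratrol raised p53, stress response, autophagy and NRF2 genes and lowered proliferation genes. Heat shock genes, with 2 higher, 4 lower and 4 not called, held no list call (adjusted p = 0.337). The p53 target genes had 15 higher, 0 lower and 2 not called of 17 (15 and 0 adjusted over the list alone). For p53 target genes camera gave adjusted p = 5.73e-11, and adjusted p = 0.0187 with an estimated correlation. Trp53inp1, Phlda3 and Bbc3 (2.46 ± 0.31, adjusted p = 0.000108) moved most. Integrated stress response and unfolded protein response genes had 12 higher, 2 lower and 10 not called of 24 (12 and 2 adjusted over the list alone). For integrated stress response genes camera gave adjusted p = 0.000482, and adjusted p = 0.0211 with an estimated correlation. Ddit4, Trib3 and Chac1 moved most. Autophagy genes had 16 higher, 1 lower and 8 not called of 25 (16 and 1 adjusted over the list alone). For autophagy genes camera gave adjusted p = 0.000103, and adjusted p = 0.0187 with an estimated correlation. Sqstm1 (2.17 ± 0.12, adjusted p = 5.31e-07) and Ulk1 (1.94 ± 0.11, adjusted p = 4.91e-07) moved most. NRF2 and antioxidant genes had 10 higher, 2 lower and 9 not called of 21 (11 and 4 adjusted over the list alone). For NRF2 and antioxidant genes camera gave adjusted p = 0.00350, and adjusted p = 0.0564 with an estimated correlation. Srxn1 (2.64 ± 0.11, adjusted p = 1.99e-07) and Slc7a11 (1.75 ± 0.20, adjusted p = 6.71e-05) moved most. G2 and mitosis genes had 0 higher, 16 lower and 4 not called of 20 (0 and 17 adjusted over the list alone). For G2 and mitosis genes camera gave adjusted p = 9.40e-10, and adjusted p = 0.0211 with an estimated correlation. Plk1 (-2.21 ± 0.18, adjusted p = 7.95e-06) and Cdc20 (-1.65 ± 0.15, adjusted p = 1.63e-05) moved most. S-phase and DNA replication genes had 0 higher, 15 lower and 9 not called of 24 (0 and 15 adjusted over the list alone). For S-phase genes camera gave adjusted p = 4.49e-05, and adjusted p = 0.0211 with an estimated correlation. Uhrf1 (-0.95 ± 0.11, adjusted p = 7.02e-05) moved most.

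Sterol and sugar metabolism genes were lower under resveratrol alone. Cholesterol synthesis and uptake genes had 0 higher, 16 lower and 6 not called of 22 (0 and 18 adjusted over the list alone). For cholesterol synthesis genes camera gave adjusted p = 1.25e-07, and adjusted p = 0.0716 with an estimated correlation. Hmgcs1 (-1.37 ± 0.15, adjusted p = 5.83e-05) was among those called. Glycolysis genes had 0 higher, 12 lower and 5 not called of 17 (0 and 12 adjusted over the list alone). For glycolysis genes camera gave adjusted p = 0.000202, and adjusted p = 0.280 with an estimated correlation. Slc16a3 (-1.36 ± 0.15, adjusted p = 5.52e-05) moved most. Oxidative phosphorylation genes had 0 higher, 10 lower and 15 not called of 25 (0 and 10 adjusted over the list alone). Camera gave adjusted p = 0.0103, and adjusted p = 0.416 with an estimated correlation. Sdhd (-0.73 ± 0.13, adjusted p = 0.00113) moved most. Quantile normalization removed the oxidative phosphorylation call (adjusted p = 0.927). Macrophage identity markers had 0 higher, 6 lower and 5 not called of 11 (0 and 6 adjusted over the list alone). Camera gave adjusted p = 0.00389, and adjusted p = 0.143 with an estimated correlation. Fcgr1 (-1.78 ± 0.11, adjusted p = 1.01e-06) moved most.

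Several inflammatory lists were lower without bacteria present. Chemokines had 0 higher, 6 lower and 5 not called of 11 (0 and 6 adjusted over the list alone). For chemokines camera gave adjusted p = 0.00619, and adjusted p = 0.243 with an estimated correlation. Ccl2, Ccl4 (-2.43 ± 0.30, adjusted p = 9.45e-05) and Ccl3 (-2.03 ± 0.31, adjusted p = 0.000413) moved most. Interferon-stimulated genes had 1 higher, 12 lower and 5 not called of 18 (1 and 12 adjusted over the list alone). Camera gave adjusted p = 0.000233, and adjusted p = 0.0716 with an estimated correlation. Oas3 (-1.90 ± 0.12, adjusted p = 1.19e-06) moved most. Immediate-early and MAPK feedback genes had 0 higher, 9 lower and 9 not called of 18 (0 and 10 adjusted over the list alone). For immediate-early genes camera gave adjusted p = 0.000202, and adjusted p = 0.216 with an estimated correlation. Egr2, Egr3 (-2.44 ± 0.12, adjusted p = 2.17e-07) and Fos (-1.66 ± 0.17, adjusted p = 3.88e-05) moved most. The other 13 lists held no call. NF-kB feedback and signalling genes had 5 higher, 3 lower and 12 not called of 20 (5 and 3 adjusted over the list alone). For NF-kB genes camera gave adjusted p = 0.974. Nfkbid (-2.20 ± 0.23, adjusted p = 4.18e-05) and Tnfaip2 (1.88 ± 0.10, adjusted p = 4.42e-07) moved most. Their test turned upward under quantile normalization. Lysosome genes had 2 higher, 1 lower and 20 not called of 23 (1 and 0 adjusted over the list alone). For lysosome genes camera gave adjusted p = 0.898. Mcoln1 (0.65 ± 0.12, adjusted p = 0.00177) moved most. Quantile normalization gave them adjusted p = 0.00371. Sirtuins and mitochondrial biogenesis genes had 6 higher, 3 lower and 6 not called of 15 (7 and 3 adjusted over the list alone). Camera gave adjusted p = 0.286. Nrf1 (-1.04 ± 0.09, adjusted p = 1.16e-05) moved most. Aryl hydrocarbon receptor targets had 1 higher, 1 lower and 1 not called of 3 (1 and 1 adjusted over the list alone). Camera gave adjusted p = 0.817. Nfe2l2 (-0.67 ± 0.13, adjusted p = 0.00169) moved most. Cyp1a1, a classic target of that receptor, had 2 reads over the resveratrol libraries.

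Altogether 4557 genes were called between resveratrol and untreated cells, 2181 higher and 2376 lower (409 and 445 at an absolute log2 fold change of at least 1). Of all tested genes 6366 (54.4%, chance 10%) had no overlap. The higher share was 47.9%, against 64.8% under equal sums and 69.2% under own totals, with the median of all genes moved by 0.14 and 0.18. More genes had a read in the resveratrol libraries (19801, 18256 and 19652) than in the untreated ones (17685, 17522 and 17794).

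In infected cells, resveratrol lowered part of the cytokine response and raised another part. Il1b fell from 49.7 ± 10.1 to 8.88 ± 2.11 FPKM (-2.37 ± 0.17, adjusted p = 3.15e-06) and Il6 from 16.5 ± 5.85 to 1.30 ± 0.501 (-2.90 ± 0.21, adjusted p = 2.83e-06). Il10 fell from 4.23 ± 1.10 to 0.213 ± 0.199 FPKM (-2.10 ± 0.18, adjusted p = 9.36e-06) and Il33 from 79.6 ± 19.0 to 4.65 ± 0.395 (-3.81 ± 0.15, adjusted p = 3.74e-08). Il12b, a subunit of interleukin-12 and interleukin-23, rose from 0.308 ± 0.174 to 26.4 ± 6.94 FPKM (4.37 ± 0.17, adjusted p = 3.74e-08). Nos2, the inducible nitric oxide synthase, rose from 22.8 ± 4.77 to 107 ± 15.5 FPKM (2.18 ± 0.15, adjusted p = 1.70e-06) and Cxcl10 from 0.789 ± 0.355 to 9.72 ± 3.01 (2.56 ± 0.21, adjusted p = 7.07e-06). Tnf (104 ± 14.2 and 142 ± 28.7 FPKM, 0.44 ± 0.25, adjusted p = 0.180) and Ccl5 (-0.18 ± 0.44, adjusted p = 0.777) were not called. The same held for Hmox1 (0.12 ± 0.15, adjusted p = 0.560) and Sirt1 (0.31 ± 0.15, adjusted p = 0.124). Ptgs2 was lower (-0.50 ± 0.17, adjusted p = 0.0305) and Cdkn1a higher (1.33 ± 0.15, adjusted p = 4.64e-05).

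Behind Il12b, the largest rise was that of Mfsd13a, from 8.58 ± 1.67 to 161 ± 9.14 FPKM (4.10 ± 0.13, adjusted p = 8.23e-09). Gadd45a (3.05 ± 0.26, adjusted p = 6.93e-06), Chac1 (2.96 ± 0.17, adjusted p = 5.41e-07) and Pdcd4 (2.94 ± 0.19, adjusted p = 1.46e-06) followed, then Tnfaip2 (2.83 ± 0.10, adjusted p = 1.50e-08). Cd93 fell the most, from 37.1 ± 5.88 to 0.702 ± 0.225 FPKM (-4.48 ± 0.14, adjusted p = 8.23e-09). After Il33 came the thrombomodulin gene Thbd (-3.47 ± 0.11, adjusted p = 9.55e-09), Osbp2 (-3.25 ± 0.11, adjusted p = 1.16e-08) and Carmil1 (-3.14 ± 0.13, adjusted p = 3.74e-08). On assembly GRCm38, Il1b lay at chromosome 2, start 129364570, end 129371139, ENSMUSG00000027398, and Il6 at chromosome 5, start 30013114, end 30019981, ENSMUSG00000025746. Il12b lay at chromosome 11, start 44400063, end 44414033, ENSMUSG00000004296, and Nos2 at chromosome 11, start 78920787, end 78960254, ENSMUSG00000020826. Thbd (chromosome 2, start 148404466, end 148408188, ENSMUSG00000074743) and Cd93 (chromosome 2, start 148436640, end 148443563, ENSMUSG00000027435) are neighbours.

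In infected cells given resveratrol proliferation genes fell. Heat shock genes, with 3 higher, 6 lower and 1 not called, held no list call (adjusted p = 0.364). G2 and mitosis genes had 0 higher, 20 lower and 0 not called of 20 (0 and 20 adjusted over the list alone). For G2 and mitosis genes camera gave adjusted p = 5.17e-13, and adjusted p = 0.0121 with an estimated correlation. Ccnb1 (-2.23 ± 0.13, adjusted p = 5.12e-07) and Ccna2 (-1.99 ± 0.14, adjusted p = 1.81e-06) moved most. S-phase and DNA replication genes had 0 higher, 22 lower and 2 not called of 24 (0 and 23 adjusted over the list alone). For S-phase genes camera gave adjusted p = 1.29e-10, and adjusted p = 0.00779 with an estimated correlation. Ccne2 (-1.72 ± 0.24, adjusted p = 0.000194) and Rrm2 (-1.49 ± 0.10, adjusted p = 1.85e-06) moved most. Integrated stress response and unfolded protein response genes had 14 higher, 1 lower and 9 not called of 24 (14 and 2 adjusted over the list alone). For integrated stress response genes camera gave adjusted p = 0.000227, and adjusted p = 0.0121 with an estimated correlation. Chac1 and Ddit4 (2.81 ± 0.25, adjusted p = 9.62e-06) moved most. Autophagy genes had 15 higher, 0 lower and 10 not called of 25 (15 and 0 adjusted over the list alone). For autophagy genes camera gave adjusted p = 0.000227, and adjusted p = 0.0121 with an estimated correlation. Calcoco1 (2.03 ± 0.19, adjusted p = 1.24e-05) and Ulk1 (2.02 ± 0.11, adjusted p = 3.12e-07) moved most. The p53 target genes had 13 higher, 0 lower and 4 not called of 17 (13 and 1 adjusted over the list alone). For p53 target genes camera gave adjusted p = 3.50e-05, and adjusted p = 0.0569 with an estimated correlation. Trp53inp1 (2.37 ± 0.15, adjusted p = 1.08e-06) and Bbc3 (2.32 ± 0.31, adjusted p = 0.000141) moved most. NRF2 and antioxidant genes had 5 higher, 0 lower and 16 not called of 21 (5 and 0 adjusted over the list alone). For NRF2 and antioxidant genes camera gave adjusted p = 0.0282, and adjusted p = 0.109 with an estimated correlation. Srxn1 (1.68 ± 0.11, adjusted p = 1.68e-06) moved most. NF-kB feedback and signalling genes had 11 higher, 2 lower and 7 not called of 20 (11 and 2 adjusted over the list alone). For NF-kB genes camera gave adjusted p = 0.00205, and adjusted p = 0.109 with an estimated correlation. Tnfaip2 and Nfkbie (1.59 ± 0.12, adjusted p = 2.82e-06) moved most. Histone genes took 0.0259% of summed FPKM in doubly treated and 0.00964% in infected cells, with an exact permutation p of 0.1, the smallest possible here (adjusted p = 0.25).

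Inflammatory lists in this paragraph were not called as lists against infection alone. Inflammatory cytokines had 5 higher, 5 lower and 5 not called of 15 (5 and 5 adjusted over the list alone). For inflammatory cytokines camera gave adjusted p = 0.723. Il12b, Il6 and Il1a (-2.63 ± 0.17, adjusted p = 1.26e-06) moved most. Chemokines had 1 higher, 5 lower and 5 not called of 11 (1 and 5 adjusted over the list alone). For chemokines camera gave adjusted p = 0.124. Cxcl10 and Ccl2 (-1.76 ± 0.25, adjusted p = 0.000236) moved most. Own totals gave the chemokines adjusted p = 0.0492. Interferon-stimulated genes had 4 higher, 7 lower and 7 not called of 18 (5 and 8 adjusted over the list alone). For interferon-stimulated genes camera gave adjusted p = 0.703, and median, mean and test differed in sign. Ifit3 (-1.23 ± 0.18, adjusted p = 0.000282) moved most. Antimicrobial effectors had 7 higher, 1 lower and 7 not called of 15 (8 and 2 adjusted over the list alone). Camera gave adjusted p = 0.113. Nos2 and Lcn2 (1.65 ± 0.32, adjusted p = 0.00182) moved most. Quantile normalization gave them adjusted p = 0.0376.

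Cholesterol synthesis and uptake genes had 2 higher, 12 lower and 8 not called of 22 (2 and 13 adjusted over the list alone). For cholesterol synthesis genes camera gave adjusted p = 0.0192, and adjusted p = 0.488 with an estimated correlation. Hmgcs1 (-1.25 ± 0.15, adjusted p = 8.80e-05) moved most. Quantile normalization removed this call (adjusted p = 0.0727). Osteoclast markers had 0 higher, 2 lower and 0 not called of 2 (0 and 2 adjusted over the list alone). For osteoclast markers camera gave adjusted p = 0.0135, and adjusted p = 0.0833 with an estimated correlation. Nfatc1 (-1.58 ± 0.13, adjusted p = 5.89e-06) and Dcstamp (-1.54 ± 0.15, adjusted p = 2.16e-05) moved most. Oxidative phosphorylation genes had 0 higher, 6 lower and 19 not called of 25 (0 and 4 adjusted over the list alone). Camera gave adjusted p = 0.179. Atp5c1 (-0.59 ± 0.11, adjusted p = 0.00101) moved most. Under own totals 2 of these were higher and 1 lower. Immediate-early, pattern recognition, glycolysis and liver X receptor lists held no call.

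Counted over all genes, 4960 were called between infected cells with and without resveratrol, 2558 higher and 2402 lower (505 and 497 at an absolute log2 fold change of at least 1). No overlap was found for 5727 (48.9%, chance 10%). The higher share of 51.6% became 68.0% under equal sums and 69.4% under own totals (all-gene median moved by 0.15 and 0.17). Log2 fold changes correlated with GC content at a rho of 0.301 across genes.

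**Figure D3:**
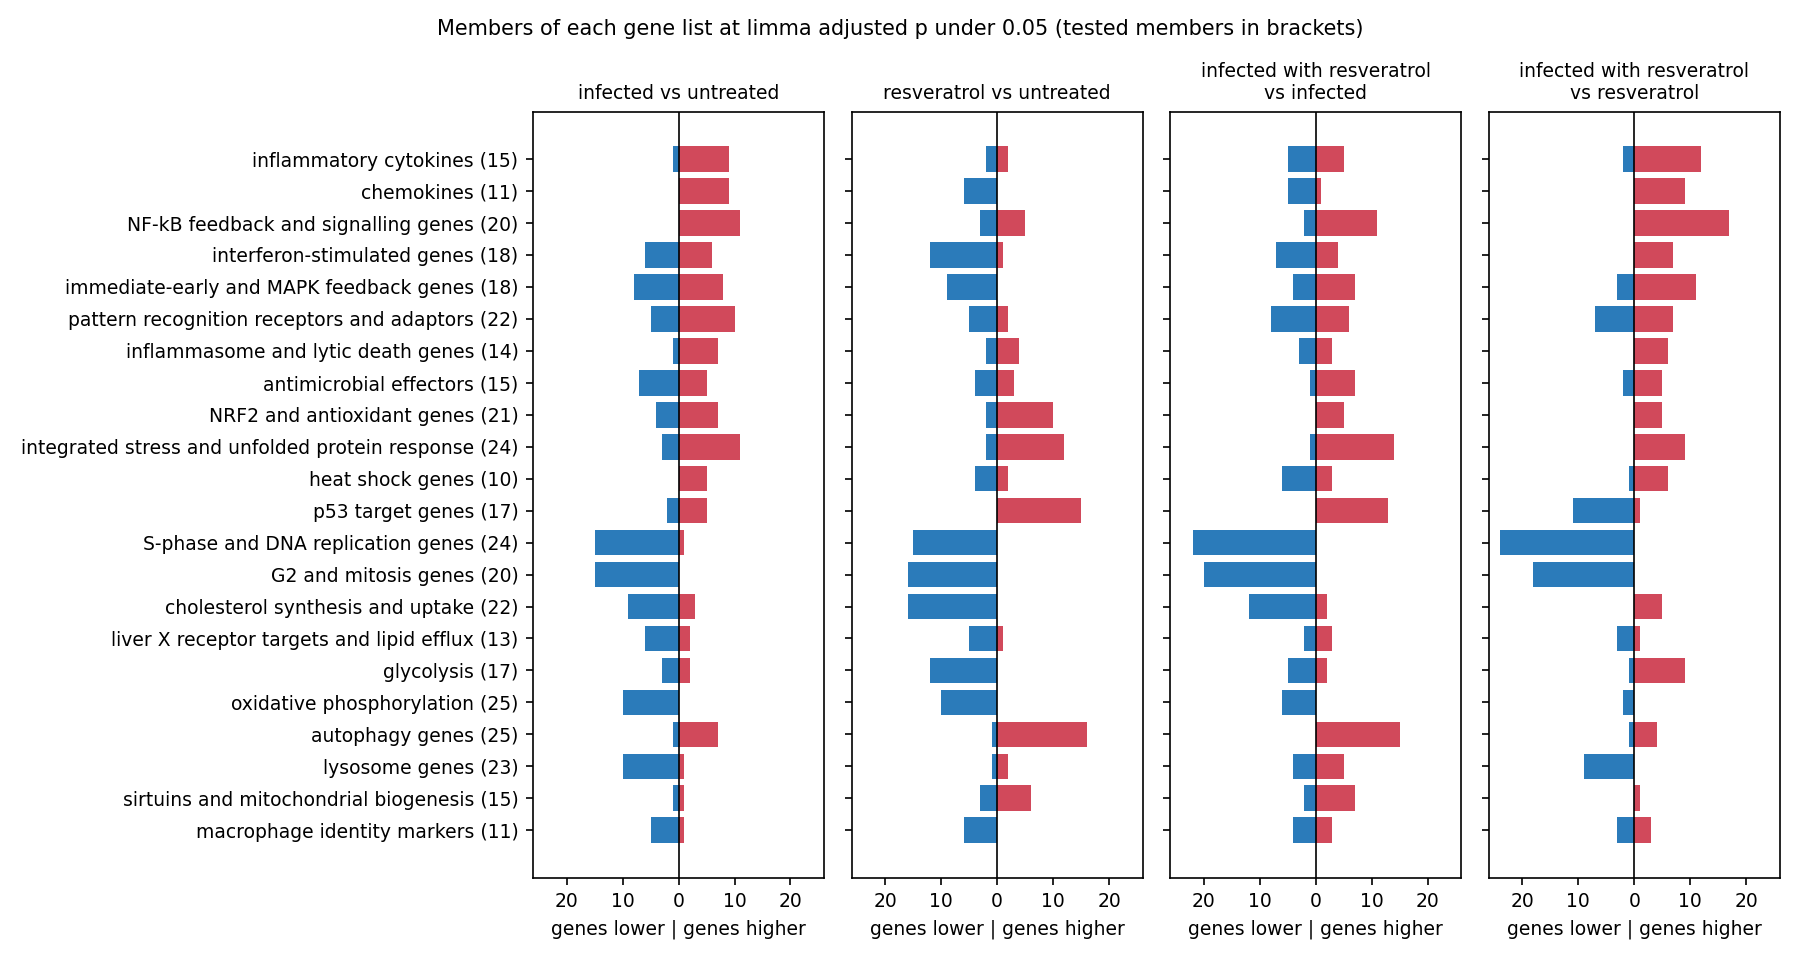
Number of genes of each list called higher (right) or lower (left) at a limma adjusted p under 0.05 in 4 comparisons, with the number of tested genes in brackets. In infected cells given resveratrol against infected cells, 20 of 20 G2 and mitosis genes were lower and 15 of 25 autophagy genes higher.

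Of the 2012 genes that infection raised, 817 (40.6%) were lower in infected cells given resveratrol than in infected cells, Il1b and Il33 among them, 286 (14.2%) such as Nos2 were higher, and 909 were not called. Of the 2149 genes that infection lowered, 783 (36.4%) such as Egr1 were higher with resveratrol, 341 such as Ccna2 were lower, and 1025 were not called. Independent calls would give 413 and 470 genes in the opposing classes, which held 1600. These comparisons share the infected libraries, which alone opposes their fold changes. In 50 simulations without group effects sharing gave a covariance of -0.0216 (observed -0.131) and r = -0.504 (observed -0.332). The 6 divisions of the infected libraries between the comparisons gave a mean covariance of -0.0916 and a mean r of -0.209 (-0.251 to -0.130). Gene counts were not corrected for sharing, and division keeps shifts common to infected libraries, as in GC content (rho -0.366, 0.301). Genes moved further in the direction of infection numbered 627 (417 without untreated library 1). Without the libraries numbered 2 (chosen afterwards) 773 opposed infection and 315 went further.

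Infection with resveratrol present, taken against resveratrol alone, again raised Csf3 (0.0693 ± 0.0580 to 157 ± 49.1 FPKM, 7.15 ± 0.20, adjusted p = 9.48e-10) and Nos2 (0.0823 ± 0.0140 to 107 ± 15.5 FPKM, 6.62 ± 0.15, adjusted p = 2.38e-10). Hcar2 (6.16 ± 0.15, adjusted p = 5.77e-10), Ptgs2 (6.01 ± 0.17, adjusted p = 9.48e-10) and Il1rn (5.99 ± 0.13, adjusted p = 2.38e-10) came next. Fosb (-2.88 ± 0.20, adjusted p = 1.79e-06), the chemokine receptor gene Cxcr4 (-2.66 ± 0.15, adjusted p = 3.65e-07) and Fos (-2.04 ± 0.17, adjusted p = 8.06e-06) fell the most. Tnf rose from 26.4 ± 10.0 to 142 ± 28.7 FPKM (2.44 ± 0.25, adjusted p = 3.37e-05) and Il1b from 0.0758 ± 0.0668 to 8.88 ± 2.11 (3.18 ± 0.17, adjusted p = 2.47e-07). Cxcl10 (2.63 ± 0.21, adjusted p = 5.54e-06), Hmox1 (2.27 ± 0.15, adjusted p = 1.16e-06) and Ccl5 (2.61 ± 0.44, adjusted p = 0.00126) rose too. Il12b and Il6 had no read with resveratrol alone and stood at least 1052-fold and at least 64.5-fold higher. Il10 (0.27 ± 0.18, adjusted p = 0.331), Cdkn1a (0.26 ± 0.15, adjusted p = 0.243) and Sirt1 (0.13 ± 0.15, adjusted p = 0.586) were not called.

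Inflammatory lists rose with infection under resveratrol as well. NF-kB feedback and signalling genes had 17 higher, 0 lower and 3 not called of 20 (17 and 0 adjusted over the list alone). For NF-kB genes camera gave adjusted p = 7.09e-14, and adjusted p = 0.00520 with an estimated correlation. Zc3h12a (3.64 ± 0.18, adjusted p = 1.43e-07) moved most. Chemokines had 9 higher, 0 lower and 2 not called of 11 (9 and 0 adjusted over the list alone). For chemokines camera gave adjusted p = 3.54e-10, and adjusted p = 0.0196 with an estimated correlation. Ccl4 (5.61 ± 0.30, adjusted p = 1.94e-07) and Ccl3 (5.21 ± 0.31, adjusted p = 4.35e-07) moved most. Inflammatory cytokines had 12 higher, 2 lower and 1 not called of 15 (12 and 2 adjusted over the list alone). Camera gave adjusted p = 8.58e-10, and adjusted p = 0.0853 with an estimated correlation. Csf3 and Il12b (4.74 ± 0.17, adjusted p = 8.60e-09) moved most. Interferon-stimulated genes had 7 higher, 0 lower and 11 not called of 18 (8 and 1 adjusted over the list alone). Camera gave adjusted p = 0.000593, and adjusted p = 0.0853 with an estimated correlation. Isg15 (2.95 ± 0.21, adjusted p = 1.84e-06) moved most. Immediate-early and MAPK feedback genes had 11 higher, 3 lower and 4 not called of 18 (11 and 3 adjusted over the list alone). Camera gave adjusted p = 0.000208, and adjusted p = 0.154 with an estimated correlation. Dusp5 (3.88 ± 0.11, adjusted p = 9.48e-10) moved most. Inflammasome and lytic death genes had 6 higher, 0 lower and 8 not called of 14 (6 and 0 adjusted over the list alone). Camera gave adjusted p = 0.0144, and adjusted p = 0.162 with an estimated correlation. Nlrp3 (1.35 ± 0.14, adjusted p = 4.53e-05) moved most. Alternative activation and anti-inflammatory genes had 4 higher, 1 lower and 3 not called of 8 (4 and 1 adjusted over the list alone). Camera gave adjusted p = 0.00107, and adjusted p = 0.0853 with an estimated correlation. Il1rn and Socs3 (5.12 ± 0.19, adjusted p = 9.24e-09) moved most.

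Integrated stress response and unfolded protein response genes had 9 higher, 0 lower and 15 not called of 24 (10 and 0 adjusted over the list alone). Camera gave adjusted p = 0.00102, and adjusted p = 0.0196 with an estimated correlation. Cebpb (1.95 ± 0.39, adjusted p = 0.00362) moved most. Quantile normalization removed this call (adjusted p = 0.0522). Heat shock genes had 6 higher, 1 lower and 3 not called of 10 (7 and 1 adjusted over the list alone). For heat shock genes camera gave adjusted p = 0.0103, and adjusted p = 0.123 with an estimated correlation. Hspa1b (1.38 ± 0.17, adjusted p = 0.000112) moved most. Quantile normalization removed this call as well (adjusted p = 0.0785). S-phase and DNA replication genes had 0 higher, 24 lower and 0 not called of 24 (0 and 24 adjusted over the list alone). For S-phase genes camera gave adjusted p = 1.22e-15, and adjusted p = 0.00182 with an estimated correlation. Mcm6 (-1.22 ± 0.14, adjusted p = 9.06e-05) moved most. G2 and mitosis genes had 0 higher, 18 lower and 2 not called of 20 (0 and 20 adjusted over the list alone). For G2 and mitosis genes camera gave adjusted p = 7.06e-13, and adjusted p = 0.0160 with an estimated correlation. Kif11 (-1.66 ± 0.19, adjusted p = 7.97e-05) moved most. Lysosome genes had 0 higher, 9 lower and 14 not called of 23 (0 and 10 adjusted over the list alone). For lysosome genes camera gave adjusted p = 0.000402, and adjusted p = 0.0184 with an estimated correlation. Lipa (-1.14 ± 0.16, adjusted p = 0.000363) moved most. The p53 target genes had 1 higher, 11 lower and 5 not called of 17 (1 and 11 adjusted over the list alone). For p53 target genes camera gave adjusted p = 0.000814, and adjusted p = 0.0853 with an estimated correlation. Trp53inp1 (-1.54 ± 0.15, adjusted p = 2.13e-05) and Plk2 (1.39 ± 0.11, adjusted p = 3.82e-06) moved most. Oxidative phosphorylation genes had 0 higher, 2 lower and 23 not called of 25 (0 and 2 adjusted over the list alone). Camera gave adjusted p = 0.0146, and adjusted p = 0.408 with an estimated correlation. Atp5c1 (-0.45 ± 0.11, adjusted p = 0.00896) moved most. Glycolysis genes had 9 higher, 1 lower and 7 not called of 17 (9 and 1 adjusted over the list alone). For glycolysis genes camera gave adjusted p = 9.17e-06, and adjusted p = 0.154 with an estimated correlation. Pfkfb3 (2.72 ± 0.09, adjusted p = 3.60e-09) moved most. The marker list that S100a8 alone represents gave adjusted p = 0.0391, and adjusted p = 0.123 with an estimated correlation. The other 10 lists held no call.

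This comparison called 2919 genes, 1530 higher and 1389 lower (415 and 238 at an absolute log2 fold change of at least 1), and 4660 (39.8%, chance 10%) had no overlap. The higher share was 52.4%, 28.8% under equal sums and 29.3% under own totals (all-gene median moved by -0.16 under both). Infection responses with and without resveratrol correlated at r = 0.604 across genes with a slope of 0.536. Genes higher in both numbered 873 and genes lower in both 836 (263 and 255 under independence), Csf3 and Uhrf1 among them. Opposite directions were seen for 79 (520 under independence). Resveratrol responses with and without infection correlated at r = 0.589 with a slope of 0.625. They shared direction for 1440 and 1346 genes (477 and 488 under independence), such as Chac1 and Plk1, and opposed each other for 112 (967).

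**Figure D4:**
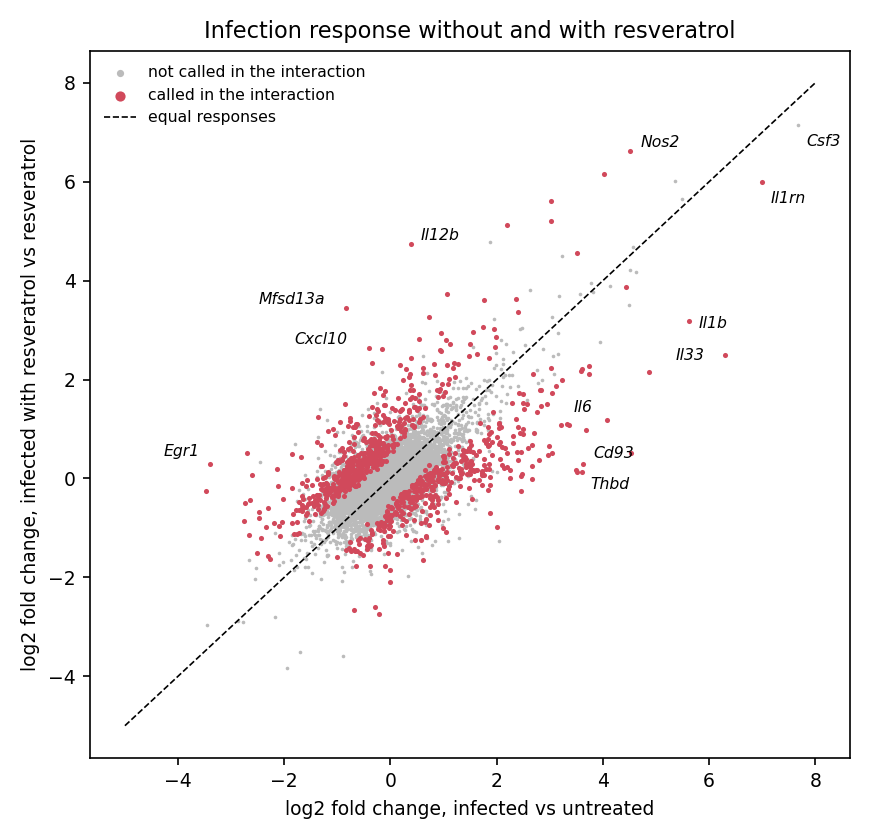
Log2 fold change on infection without resveratrol (horizontal axis) and with resveratrol (vertical axis) for the 11706 tested genes, 1 point per gene. Red points are the 954 genes called for the interaction, the dashed line marks equal responses, and r is 0.604 with Il33 and Thbd below the line and Il12b and Nos2 above it.

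Against untreated cells, doubly treated cells had Csf3 (7.21 ± 0.20, adjusted p = 9.39e-10), Nos2 (6.70 ± 0.15, adjusted p = 4.18e-10) and S100a8 (5.81 ± 0.58, adjusted p = 1.11e-05) at the top. Hcar2 (5.53 ± 0.15, adjusted p = 9.39e-10) and Ptgs2 (4.86 ± 0.17, adjusted p = 4.36e-09) followed. Plau (-4.21 ± 0.17, adjusted p = 1.30e-08), Fosb (-3.87 ± 0.20, adjusted p = 8.88e-08) and Fos (-3.69 ± 0.17, adjusted p = 4.34e-08) were lowest. Tnf (0.84 ± 0.25, adjusted p = 0.0173), Il1b (3.25 ± 0.17, adjusted p = 1.07e-07) and Cxcl10 (2.16 ± 0.21, adjusted p = 1.09e-05) were higher. So were Ccl5 (2.69 ± 0.44, adjusted p = 0.000452), Hmox1 (3.87 ± 0.15, adjusted p = 1.21e-08), Cdkn1a (2.51 ± 0.15, adjusted p = 1.86e-07) and Sirt1 (0.65 ± 0.15, adjusted p = 0.00468). Il6 stood at least 55.6-fold and Il12b at least 907-fold above untreated cells without a read, and Il10 was not called (0.01 ± 0.18, adjusted p = 0.984).

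Lists were also tested between doubly treated and untreated cells. G2 and mitosis genes had 0 higher, 20 lower and 0 not called of 20 (0 and 20 adjusted over the list alone). For G2 and mitosis genes camera gave adjusted p = 2.81e-15, and adjusted p = 0.00721 with an estimated correlation. Plk1 (-3.16 ± 0.18, adjusted p = 1.61e-07) moved most. S-phase and DNA replication genes had 0 higher, 24 lower and 0 not called of 24 (0 and 24 adjusted over the list alone). For S-phase genes camera gave adjusted p = 1.49e-14, and adjusted p = 0.00254 with an estimated correlation. Uhrf1 (-2.01 ± 0.11, adjusted p = 1.20e-07) moved most. NF-kB feedback and signalling genes had 18 higher, 1 lower and 1 not called of 20 (19 and 1 adjusted over the list alone). For NF-kB genes camera gave adjusted p = 6.14e-10, and adjusted p = 0.00721 with an estimated correlation. Zc3h12a (3.21 ± 0.18, adjusted p = 1.61e-07) moved most. Integrated stress response and unfolded protein response genes had 15 higher, 2 lower and 7 not called of 24 (15 and 2 adjusted over the list alone). For integrated stress response genes camera gave adjusted p = 5.40e-06, and adjusted p = 0.00721 with an estimated correlation. Ddit4 (4.39 ± 0.25, adjusted p = 1.42e-07) moved most. Autophagy genes had 16 higher, 1 lower and 8 not called of 25 (17 and 1 adjusted over the list alone). For autophagy genes camera gave adjusted p = 5.71e-05, and adjusted p = 0.00721 with an estimated correlation. Sqstm1 (2.83 ± 0.12, adjusted p = 2.04e-08) moved most. The p53 target genes had 13 higher, 0 lower and 4 not called of 17 (13 and 0 adjusted over the list alone). For p53 target genes camera gave adjusted p = 2.20e-06, and adjusted p = 0.0296 with an estimated correlation. Cdkn1a moved most. NRF2 and antioxidant genes had 11 higher, 2 lower and 8 not called of 21 (11 and 4 adjusted over the list alone). For NRF2 and antioxidant genes camera gave adjusted p = 0.00259, and adjusted p = 0.0443 with an estimated correlation. Slc7a11 (3.97 ± 0.20, adjusted p = 6.64e-08) moved most.

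A further 8 lists were called with the preset correlation alone. They were inflammatory cytokines, chemokines, inflammasome and lytic death genes, alternative activation and anti-inflammatory genes, cholesterol synthesis and uptake, oxidative phosphorylation, lysosome genes and macrophage identity markers. Their results ran from adjusted p = 0.0580 to adjusted p = 0.195 with an estimated correlation. Quantile normalization removed the calls of lysosome genes (adjusted p = 0.194) and macrophage identity markers (adjusted p = 0.0634). The other 11 lists held no call.

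Between doubly treated and untreated cells 5309 genes were called, 2689 higher and 2620 lower (724 and 666 at an absolute log2 fold change of at least 1), and 7473 (63.8%, chance 10%) had no overlap. The higher share of 50.6% was 49.4% under equal sums and 54.1% under own totals, and the all-gene median moved by -0.01 and 0.02. For any of these 3 against 3 comparisons the smallest p an exact permutation can give is 0.1.

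The interaction term tested departure from additive responses, positive where infected cells given resveratrol lay above the sum of the separate effects. Above that sum were Il12b (4.37 ± 0.25, adjusted p = 2.54e-06), Mfsd13a (4.27 ± 0.18, adjusted p = 4.75e-07), Egr1 (3.69 ± 0.28, adjusted p = 2.22e-05) and Egr2 (3.23 ± 0.19, adjusted p = 2.70e-06). Cxcl10 (3.03 ± 0.30, adjusted p = 0.000175), Nos2 (2.11 ± 0.21, adjusted p = 0.000173) and Tnf (2.04 ± 0.35, adjusted p = 0.00536) lay there too. Below it were Il33 (-3.82 ± 0.22, adjusted p = 2.54e-06), Thbd (-3.48 ± 0.16, adjusted p = 4.75e-07), Osbp2 (-3.39 ± 0.15, adjusted p = 4.75e-07) and Cd93 (-3.35 ± 0.19, adjusted p = 2.56e-06). The same held for Il6 (-2.90 ± 0.30, adjusted p = 0.000179), Il1b (-2.44 ± 0.25, adjusted p = 0.000179) and Il10 (-1.84 ± 0.26, adjusted p = 0.00164), and for Hmox1 (-1.48 ± 0.21, adjusted p = 0.00204) and Cdkn1a (-0.93 ± 0.21, adjusted p = 0.0206). For Il6, Il10, Il12b and Il33, which had no read in at least 1 group, the fitted value depends on the pseudocount of 1. The same applies to Nos2, with few reads in untreated cells, which gave 1.70 with a pseudocount of 0.1, and Il10 was not called there (adjusted p = 0.0969). With voom on recovered reads the call was lost for Nos2 (0.73, adjusted p = 0.637), Il10 (adjusted p = 0.541), Il6 (adjusted p = 0.187), Il1b (adjusted p = 0.126) and Il33 (adjusted p = 0.0518). Ptgs2 (0.65 ± 0.23, adjusted p = 0.115), Ccl5 (-0.26 ± 0.63, adjusted p = 0.824) and Sirt1 (-0.21 ± 0.22, adjusted p = 0.575) were not called.

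The interaction called 10 of 26 lists. NF-kB feedback and signalling genes had 8 higher, 0 lower and 12 not called of 20 (9 and 0 adjusted over the list alone). For NF-kB genes camera gave adjusted p = 7.21e-07, and adjusted p = 0.0488 with an estimated correlation. Nfkbid (1.66 ± 0.33, adjusted p = 0.0107) and Zc3h12a (1.27 ± 0.26, adjusted p = 0.0127) lay furthest from additivity. Immediate-early and MAPK feedback genes had 8 higher, 1 lower and 9 not called of 18 (10 and 1 adjusted over the list alone). For immediate-early genes camera gave adjusted p = 7.21e-07, and adjusted p = 0.159 with an estimated correlation. Egr1 and Egr2 (partly forced) lay furthest from additivity. Interferon-stimulated genes had 7 higher, 0 lower and 11 not called of 18 (10 and 1 adjusted over the list alone). Camera gave adjusted p = 9.26e-05, and adjusted p = 0.0979 with an estimated correlation. Isg15 (1.39 ± 0.30, adjusted p = 0.0154) and Usp18 (1.15 ± 0.20, adjusted p = 0.00611) lay furthest from additivity. Glycolysis genes had 5 higher, 0 lower and 12 not called of 17 (8 and 0 adjusted over the list alone). For glycolysis genes camera gave adjusted p = 9.26e-06, and adjusted p = 0.290 with an estimated correlation. Pfkfb3 (1.59 ± 0.13, adjusted p = 3.22e-05) and Hk2 (1.16 ± 0.28, adjusted p = 0.0260) lay furthest from additivity. Cholesterol synthesis and uptake genes had 5 higher, 0 lower and 17 not called of 22 (8 and 0 adjusted over the list alone). Camera gave adjusted p = 0.00101, and adjusted p = 0.290 with an estimated correlation. Mvk (1.13 ± 0.25, adjusted p = 0.0172) was among the called members. Liver X receptor targets and lipid efflux genes had 4 higher, 2 lower and 7 not called of 13 (7 and 2 adjusted over the list alone). Camera gave adjusted p = 0.0330, and adjusted p = 0.290 with an estimated correlation. Lpl (2.12 ± 0.38, adjusted p = 0.00617) and Plin2 (-1.69 ± 0.17, adjusted p = 0.000179) lay furthest from additivity. The p53 target genes had 0 higher, 8 lower and 9 not called of 17 (0 and 10 adjusted over the list alone). For p53 target genes camera gave adjusted p = 8.11e-06, and adjusted p = 0.0694 with an estimated correlation. Fas (-1.86 ± 0.32, adjusted p = 0.00483) and Trp53inp1 (-1.67 ± 0.21, adjusted p = 0.000781) lay furthest from additivity. S-phase and DNA replication genes had 0 higher, 5 lower and 19 not called of 24 (0 and 8 adjusted over the list alone). For S-phase genes camera gave adjusted p = 1.70e-05, and adjusted p = 0.0488 with an estimated correlation. Ccne2 (-1.67 ± 0.33, adjusted p = 0.0115) and Cdc6 (-0.82 ± 0.12, adjusted p = 0.00185) lay furthest from additivity. G2 and mitosis genes had 0 higher, 1 lower and 19 not called of 20 (0 and 5 adjusted over the list alone). For G2 and mitosis genes camera gave adjusted p = 0.0161, and adjusted p = 0.295 with an estimated correlation. Nusap1 (-0.86 ± 0.21, adjusted p = 0.0316) lay furthest from additivity. Pattern recognition receptors and adaptors had 0 higher, 4 lower and 18 not called of 22 (0 and 4 adjusted over the list alone). Camera gave adjusted p = 0.0469, and adjusted p = 0.446 with an estimated correlation. Clec4d (-1.43 ± 0.18, adjusted p = 0.000915) and Tlr9 (-1.32 ± 0.17, adjusted p = 0.00102) lay furthest from additivity. Quantile normalization removed this call (adjusted p = 0.0508).

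The interaction called 954 genes, 554 higher and 400 lower (222 and 189 at an absolute log2 fold change of at least 1), which makes 58.1% higher, against 59.7% under equal sums, 53.8% under own totals and 46.8% after a correction for GC content and gene length. Interaction values correlated with GC content at a rho of 0.467, and within the infected group library 3 departed from the group mean with a rho of 0.629 and library 1 with -0.507. Counts were 498, 540 and 616 without untreated library 1, 2 or 3, 519 without resveratrol library 3, 527 without doubly treated library 3, and 2006 without infected library 3.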

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

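The results below came out under 0.05 in tests of the interaction term. Both tests of a weaker infection were chosen after these results were seen. Those of regrouping, GC content and own totals were set before theirs. The term called 954 genes. Panel genes among them were Tnf (2.04), Cxcl10 (3.03), Nos2 (2.11), Il1b (-2.44), Il6 (-2.90), Il10 (-1.84), Hmox1 (-1.48) and Cdkn1a (-0.93). With voom the calls of Nos2 (0.73, adjusted p = 0.637), Il1b, Il6, Il10 and Il33 ended. Furthest above the sum were Il12b (4.37), Mfsd13a (4.27), Egr1 (3.69), Egr2 (3.23, partly forced) and Fam20c (3.23). Furthest below were Il33 (-3.82), Thbd (-3.48), Osbp2 (-3.39), Cd93 (-3.35) and Carmil1 (-3.33).

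List medians of the interaction were 0.50 for NF-kB feedback and signalling genes (Nfkbid 1.66, Zc3h12a 1.27), 0.57 for interferon-stimulated genes (Isg15 1.39, Usp18 1.15), 0.63 for immediate-early and MAPK feedback genes, 0.78 for liver X receptor targets and lipid efflux (Lpl 2.12, Plin2 -1.69), 0.58 for glycolysis (Pfkfb3 1.59, Hk2 1.16) and 0.32 for cholesterol synthesis and uptake (Mvk 1.13). They were -0.24 for pattern recognition receptors and adaptors (Clec4d -1.43, Tlr9 -1.32), -0.58 for p53 target genes (Fas -1.86, Trp53inp1 -1.67), -0.30 for S-phase and DNA replication genes (Ccne2 -1.67, Cdc6 -0.82) and -0.31 for G2 and mitosis genes (Nusap1 -0.86). With an estimated correlation only the NF-kB and S-phase lists kept the call (adjusted p = 0.0488 for both). The other 8 did not (adjusted p = 0.0694 to 0.446).

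Regrouping libraries could not weigh chance, since mixed groups carry treatment effects in their spread, which lowers counts. Among 100 random groupings of the 12 libraries, the real one included, 2 reached 954 interaction genes (highest other 1427) and 1 reached 1600 genes opposing infection (highest other 786). Each pairwise comparison has 10 splits, too few for a share under 0.05, and only the real one reached the observed count. Real counts were 4161, 4557, 4960, 2919 and 5309, the highest others 1, 1, 1, 1 and 0.

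Other explanations for the departure from additivity were then weighed. Differences in GC content between libraries may carry part of it, since 75.2% of the interaction calls (717 genes, exact interval 72.3 to 77.9%) stayed after the GC and length correction, too near the 75% set before to decide, and the median absolute value went from 0.94 to 0.80. That interval treats genes as independent, which they are not. All 954 genes kept their direction, and 1123 genes were called after the correction. Own totals kept 91.0% (868 genes) but moved the interaction of the median gene by -0.01 alone, which says nothing on the authors' scaling. A uniformly weaker infection could account for falls among induced genes. Of those, 6.84% (26 of 380 not raised by resveratrol alone) were higher with resveratrol, which left it open. Among interaction genes 36.6% (349) had a called infection response larger in size under resveratrol, 167 in the same and 182 in the opposite direction. Resveratrol alone lowered some, such as Ccl4, which enlarges the response, so the share could not decide. It was 35.1% with a pseudocount of 0.1 and 33.9% with voom.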

How the results depend on the processing

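Among named genes 1 value reversed under an alternative. Gusb under resveratrol against untreated cells went to 0.06 (0.0571, adjusted p = 0.742) under quantile normalization, and the cause was not tested. A minimum absolute log2 fold change of 1 left 876, 854, 1002, 653, 1390 and 411 genes (infected, resveratrol against untreated, doubly treated against infected, resveratrol and untreated, interaction) by construction. Array weights, whose REML estimation did not converge, gave 7496, 8466, 8672, 9323, 8966 and 7346 genes, 4220 opposing and 1606 extending infection, and correlations of 0.498 (infection) and 0.480 (resveratrol, slope 0.508). Gene-by-gene array weights, chosen after seeing the data, gave 6327 (infected) and 7023 (resveratrol) against untreated, 6550 and 8544 for doubly treated against resveratrol and untreated, 4651 for the interaction, 3111 opposing and 1142 extending. A filter on mean FPKM of at least 5 left 3004 genes for resveratrol against untreated, 1028 higher and 1976 lower. Without the libraries numbered 2, also chosen after seeing the data, 2363 genes differed between infected and untreated cells and 294 for the interaction, with 773 opposing and 315 extending, and the cause was not tested for these. Most named calls stayed under equal sums, set in advance (590 of 609), and under alternatives added after seeing the data, 588 with own totals, 602 after GC and length correction, and 601 with voom, but 535 without the libraries numbered 2. Leaving out each library gave 2863 to 4888, 3536 to 4450, 3901 to 5249, 1997 to 3226 and 4341 to 4786 genes in the pairwise order above, 498 to 2006 for the interaction, 1117 to 2224 opposing and 417 to 687 extending, correlations of 0.545 to 0.643 (infection) and 0.524 to 0.634 (resveratrol), and slopes of 0.444 to 0.595 and 0.551 to 0.666. With the replicate number as a block the counts were 4179, 4597, 5008, 2931, 5354 and 826, but nothing in the labels pairs same-numbered libraries. Their lowest correlations over the 6 pairs of groups were -0.0442, -0.268, -0.0311, -0.339, -0.0258 and 0.0819, while libraries numbered 2 correlated at 0.350, 0.405 and 0.299 between the treated groups, and libraries with different numbers at up to 0.550. The planned median-of-ratios scaling was void, since its factor was 1.0102 for all libraries.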

Other observations

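Genes below the filter were looked at after the values had been seen, and none was tested. S100a9, the partner of S100a8, had no read in the other groups and 0.877 ± 0.416 FPKM (25 reads) in doubly treated cells. Hamp, which encodes hepcidin, had 0.0483 ± 0.0837 FPKM in infected and 1.34 ± 0.722 FPKM (30 reads) in doubly treated cells. Saa3 had 0.191 ± 0.0897, 0.277 ± 0.130, 0.320 ± 0.0644 and 1.85 ± 0.814 FPKM in untreated, resveratrol, infected and doubly treated cells. Socs1, a brake on cytokine receptor signalling, ran at 0.105 ± 0.0983, 0.241 ± 0.116, 0.314 ± 0.0933 and 1.09 ± 0.306 FPKM in the same order. The autophagy receptor gene Optn stood at 0.169 ± 0.0287 and 0.986 ± 0.290 FPKM without and with resveratrol, and at 0.138 ± 0.104 and 1.00 ± 0.0886 FPKM in infected cells. Eda2r, a p53 target, went from 0.111 ± 0.0129 to 0.621 ± 0.139 FPKM with resveratrol. These were higher with resveratrol. Others, such as Mmp9, Gbp3 and Itgb3, fell in infected cells given it (Mmp9 0.728 ± 0.0916 to 0.165 ± 0.0983 FPKM).

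More patterns in the libraries were weighed. All tests here were chosen after the patterns were seen, but those of the 100 highest genes, genomic DNA and thinning before their own results. Higher and lower genes came out in nearly even numbers in each pairwise comparison, though not for resveratrol against untreated cells at a mean of at least 5 FPKM (1028 and 1976). The authors' normalization may produce this in 4 of them, since 30.6% of calls were higher in infected than untreated cells under own totals, and 69.2%, 69.4% and 29.3% for resveratrol against untreated and doubly treated against infected and resveratrol cells. Doubly treated against untreated cells stayed near even (54.1%). Mitochondrial transcripts did not account for that shift (29.5% without them), and a few abundant nuclear genes could do so in part for infected against untreated and doubly treated against resveratrol cells (40.7% and 37.2% without the 100 highest genes) but not for resveratrol against untreated or doubly treated against infected cells (68.7% and 66.6%), and doubly treated against untreated cells went to 60.1%. More genes had a read in the resveratrol libraries than in the untreated ones. Depth did not account for it, as the highest resveratrol total of 17368079 was below the highest untreated total of 17825568, nor did more reads left for the typical gene, as the lowest resveratrol library still had 17845 genes after thinning against at most 17550 in untreated libraries. Genomic DNA might contribute. Olfactory and vomeronasal receptor genes had at least 1.17 times the reads (321, 304 and 434, at most 260 in untreated libraries). These counts were unscaled and came from 48, 46 and 58 of 1740 genes (at most 38 in untreated libraries), so they could not decide. Shares of lincRNA were 0.506%, 0.287% and 0.470% (at most 0.186%). Infected libraries held 520, 416 and 352 receptor reads with 15482, 16766 and 18102 genes detected.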
